A study of Mus with 18 samples.

How the data were processed

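The series measured gene expression in RAW264.7 cells, a mouse macrophage-like line, after 6 h of treatment. Per the labels there were 18 libraries in 6 groups of 3. The groups were untreated control cells, cells given lipopolysaccharide (LPS) at 1 µg/mL, and cells given LPS together with 100 µM of caffeic acid (CA), chlorogenic acid (CGA), a cysteine adduct of caffeic acid (CACys) or a cysteine adduct of chlorogenic acid (CGACys). CGA is the quinic acid ester of caffeic acid. Per the labels the material was total RNA, and the submitters named the mm10 genome, HISAT and DESeq2 without versions. The labels did not state which program counted reads, whether the libraries kept strand, whether poly(A) RNA was selected, or which annotation release was used.

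The values deposited by the submitters were raw counts per Ensembl gene. The table held 54532 genes, of which 26742 had no count in any library. Library totals ran from 16105817 to 25624935 counts. Genes were placed on build GRCm38.p6 (mm10), and values below are for whole genes because the counts do not separate transcripts. Of the tested genes 12411 were matched to a RefSeq symbol table and 840 were not. Ensembl identifiers were kept apart where 203 of them shared 100 symbols.

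All groups were fitted in 1 model with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, which left 13251 genes holding at least 99.907% of each library's counts. Scaling used trimmed mean of M values (TMM) factors. Dispersions were estimated robustly and the common biological coefficient of variation was 5.68%. Each contrast was tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, and a gene is called changed at an adjusted p of 0.05 or less. The 10 contrasts were LPS against control, each compound with LPS against LPS alone, each adduct against its parent acid, CGA against CA, CGACys against CACys, and the adduct effect in CGA minus the adduct effect in CA. Fold changes are edgeR log2 values with standard error (SE) and 95% intervals. The SE was derived as the absolute log2 change divided by the square root of the F statistic, and the intervals were built from it. Levels are counts scaled by library size and TMM factor (CPM), given as mean ± standard deviation (SD) with n = 3 libraries per group. Where every control library had a count of 0, a floor was given from 3 counts over the group, and that floor covers counting error only.

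Gene lists were fixed from general knowledge of the pathways before the data were examined. There were 32 lists, of which 29 had at least 5 tested members. The lists called NF-kB targets and ATF4 targets below also held pathway, feedback and amino acid response genes, not targets alone. They were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2, with a correlation between genes estimated for each list and Benjamini-Hochberg adjustment over the lists. For each list the members called changed were counted with the adjustment over all genes, and again with the adjustment over the list alone. Medians over a list were not given for cytokine, chemokine and interferon lists in LPS against control, where many members had counts near 0 without LPS.

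Genes were named by a rule written before the data were examined. The rule took the 10 called protein-coding genes with the largest fold change, a mean of at least 50 counts in the higher group and no overlap between the groups. It added 2 to 4 called members of each described list with the largest fold change. It also took 16 genes in every comparison: Tnf, Il1b, Il6, Il10, Nos2, Ptgs2, Ccl2, Cxcl10, Ifnb1, Ifit1, Hmox1, Nqo1, Gclm, Slc7a11, Srxn1 and Cdkn1a. Genes named outside this rule are said to have been chosen after their values were seen. The 16 genes are given in every comparison and the others that the rule named in part. The results of 2 genes are not reported here, and both genes stayed in the counts and list tests.

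The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples. Replicate numbers were not used as pairs.

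The alternatives chosen before the data were examined were relative log expression (RLE) factors, upper-quartile factors, no expression filter, a filter of 1 CPM in 3 libraries, a replicate term, a model of only the groups compared, DESeq2 1.42.0, omission of each library in turn, and camera with a preset correlation of 0.01. List members without LPS + CA replicate 2, and the interferon list under other scaling factors, were added after the data were seen. No library was left out of the results. Transcript isoforms, allele-specific signals and RNA editing could not be measured from counts per gene and were left out.

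The method was tested on simulated counts with a spread per gene estimated from these libraries, drawn independently between genes. Changes were planted only in genes with a mean of at least 50 counts. In the design of CA with LPS against LPS, planted changes of 1.25-fold were found for 38 of 67 genes, changes of 1.5-fold for 63 of 67, and changes of 2-fold for 65 of 66, with 9 false calls. In the design of CGACys against CGA the same sizes were found for 36 of 67, 60 of 67 and 66 of 66 genes, with 6 false calls. With nothing planted there were 1 and 0 calls. A planted list shift was recovered with 0 other lists called. The simulated genes were uncorrelated, so that recovery does not test lists whose genes correlate.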

Results

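LPS separated the libraries more than any compound did. On the first principal component of all tested genes, which held 68.21% of the variance, the 3 control libraries lay apart from the 15 libraries with LPS. Among the LPS libraries alone the first component held 31.9%. It placed both cysteine adducts on one side, and both parent acids and the libraries without a compound on the other. Replicate 2 of LPS + CA stood apart from the other LPS libraries. In it the ribosomal protein genes took 4.925% of counts, against 4.173% and 4.168% in its fellow replicates, and Fth1, a ferritin gene, took 2.09% against 1.759% and 1.66%. Mitochondrial genes averaged 1.803% of counts in control and 1.412% with LPS alone, and 1.509%, 1.596%, 1.502% and 1.548% with CA, CGA, CACys and CGACys.

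**Figure D1:**
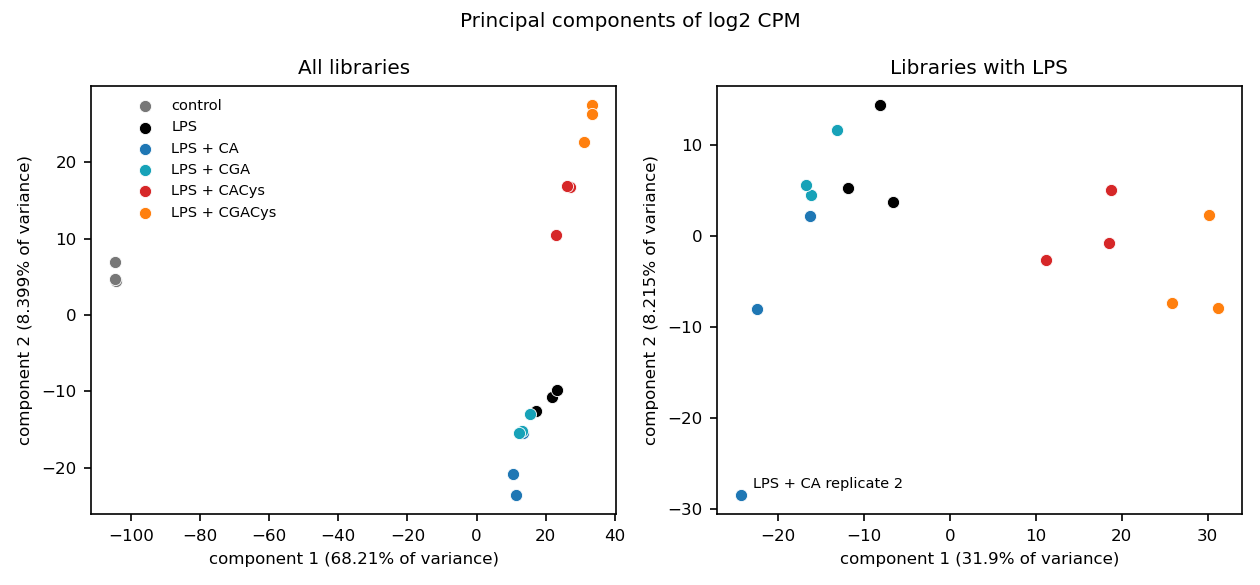
Principal components of log2 CPM for all 18 libraries (left) and for the LPS libraries (right), with the share of variance on each axis, colored by group with n = 3 each. The first axis held 68.21% on the left, where LPS parted from control. It held 31.9% on the right, where the adducts parted from their parent acids and from LPS alone.

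LPS against control asked which transcripts the endotoxin alone altered. Saa3, an acute-phase gene (ENSMUSG00000040026, chromosome 7, 46711998 to 46719615, GRCm38.p6), reached 1397 ± 79.4 CPM with LPS and 0.134 ± 0.0233 CPM in control (mean ± SD, n = 3). Nos2, which encodes inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960226), rose from 0.344 ± 0.234 to 418.5 ± 40.1 CPM, a log2 change of 10.25 (SE 0.26). Il1b, the interleukin 1 beta gene (ENSMUSG00000027398, chromosome 2, 129364569 to 129371164), rose from 0.375 ± 0.221 to 773 ± 152 CPM. Ptgs2, which encodes cyclooxygenase 2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108234), rose 48.3-fold to 2199 ± 116 CPM, and Tnf rose 22.4-fold to 969 ± 161 CPM. Cxcl3, Il12b, Csf3 and the peptidoglycan recognition gene Pglyrp3 had a count of 0 in control and rose at least 1130-fold, 858-fold, 736-fold and 278-fold. Il6 averaged 113.1 ± 17.04 CPM with LPS and 0.0360 CPM in control. The edgeR adjusted p was 9.5e-14 for Nos2, 7.44e-13 for Il1b, 2.93e-32 for Ptgs2 and 3.94e-10 for Tnf.

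Of 46 interferon-stimulated genes 46 were called higher with LPS, while the list itself had a camera adjusted p = 0.0517 with an estimated correlation. Rsad2, which encodes viperin, rose 625-fold to 1843 ± 208 CPM, and Ifit1 (ENSMUSG00000034459, chromosome 19, 34640889 to 34650009) rose from 1.55 ± 0.559 to 487 ± 68.0 CPM. The chemokine genes Ccl5 and Cxcl10 rose 744-fold and 292-fold, and Ccl2 rose 5.7-fold. Ifnb1, the interferon beta gene, averaged 0.440 ± 0.255 CPM against a count of 0, at least 8.7-fold. Il10, the gene of an anti-inflammatory cytokine, rose from 0.475 ± 0.0907 to 5.81 ± 0.293 CPM. Lists called higher by camera with an estimated correlation were inflammatory cytokines (20 of 21 members higher, adjusted p = 0.0145), chemokines (18 higher and 2 lower of 21, p = 0.0037), NF-kB targets (27 of 27, p = 0.0215), ATF4 targets (31 of 33, p = 0.00536) and iron and metal handling (14 higher and 3 lower of 20, p = 0.0331).

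Members of the NRF2 and cell cycle lists were also called with LPS. Slc7a11, the cystine transporter gene, rose 15.6-fold to 770 ± 58.8 CPM. Srxn1, the sulfiredoxin gene (ENSMUSG00000032802, chromosome 2, 152105524 to 152111376), rose 3.12-fold, Hmox1, the heme oxygenase 1 gene, 2.46-fold, Gclm 2.10-fold and Nqo1 1.57-fold. Cdkn1a, the p21 gene, rose 3.20-fold to 362 ± 30.0 CPM. Cdc6, a replication licensing gene (ENSMUSG00000017499, chromosome 11, 98907709 to 98923942), fell from 38.6 ± 1.79 to 3.81 ± 0.0678 CPM, with edgeR adjusted p = 1.72e-19. Camera called the S phase list lower (32 of 33 members lower, median log2 -1.40, adjusted p = 0.000724) and the mitosis list lower (26 of 29, median -0.38, p = 0.0037), each with an estimated correlation. NRF2 targets had 30 higher and 2 lower of 38, with adjusted p = 0.174 with an estimated correlation, and 31 higher when adjusted over the list alone. Across all genes 8243 of 13251 were called, 4056 higher and 4187 lower, of which 2486 changed at least 2-fold. The balance turned with RLE factors (4224 higher and 4022 lower), by DESeq2 (4180 and 3959) and without control replicate 1 (3880 and 3852) or 2 (3949 and 3844), and was 3428 and 4933 with upper-quartile factors. Of 5 tested fibroblast markers 4 were higher with LPS (camera adjusted p = 0.128 with an estimated correlation), and Col6a1 averaged 0.549 CPM against a count of 0 in control, at least 10.9-fold. Of 4 tested neutrophil and mast cell markers 3 were higher, and Camp averaged 2.36 CPM against a count of 0, at least 46.7-fold. The 1 tested lymphocyte marker, Pax5, was higher at 0.476 against 0.0508 CPM.

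CA with LPS against LPS alone asked what caffeic acid altered in cells given LPS. No group had a compound without LPS, and none had cysteine in place of an adduct. Effects on the LPS response thus cannot be told apart from effects that a compound has without LPS. Nos2 fell 1.73-fold, from 418.5 ± 40.1 to 242 ± 23.7 CPM (n = 3). Il1b fell 1.61-fold to 481 ± 79.9 CPM, Ccl2 1.60-fold to 283 ± 45.6 CPM and Cxcl10, an interferon-induced chemokine gene (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), 1.52-fold to 253 ± 20.9 CPM. Ifit1 fell 1.45-fold to 337 ± 29.8 CPM. Hmox1 (ENSMUSG00000005413, chromosome 8, 75093618 to 75100593) rose 1.62-fold to 3458 ± 408 CPM, Srxn1 rose 1.51-fold to 1554 ± 75.7 CPM and Nqo1, the quinone reductase gene (ENSMUSG00000003849, chromosome 8, 107388225 to 107403205), rose 1.43-fold to 43.4 ± 2.68 CPM. The edgeR adjusted p was 0.00124 for Nos2, 0.0128 for Il1b, 0.0206 for Ifit1 and 2.52e-06 for Srxn1. Tnf, with log2 -0.05 and a 95% interval of -0.44 to 0.34, Ptgs2 with 0.06 (-0.04 to 0.16), Il6 with -0.26 (adjusted p = 0.11) Il10 with -0.26 (0.364), Slc7a11 with 0.30 (0.0538) and Ifnb1 with -0.52 (0.718) were not called. Cdkn1a fell by a log2 of 0.19 (0.0255).

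Among the 10 genes with the largest fold change with CA, Il23r, an interleukin 23 receptor gene, fell from 3.83 to 1.45 CPM and Ch25h, which encodes cholesterol 25-hydroxylase, from 2.90 to 1.09 CPM. Siglec1, a macrophage sialic acid receptor gene, fell from 50.2 ± 7.22 to 22.9 ± 6.39 CPM. Sstr5, a somatostatin receptor gene (ENSMUSG00000050824, chromosome 17, 25489875 to 25497288), rose from 3.03 ± 0.709 to 7.01 ± 1.22 CPM. The neutrophil markers Ly6g and S100a8 were also higher with CA, at log2 1.44 (edgeR adjusted p = 0.00598) and 0.49 (adjusted p = 0.0411), and from 0 to 2 of the 4 tested neutrophil and mast cell markers were higher when each library was left out in turn.

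With CA the called interferon genes were lower and the called NRF2 targets higher, while camera called neither list with an estimated correlation. Of 46 interferon genes 42 were lower (median log2 -0.51, camera adjusted p = 0.0612 with an estimated correlation), and 45 when adjusted over the list alone. Of 38 NRF2 targets 27 were higher (median 0.29, adjusted p = 0.0612 with an estimated correlation), and 32 when adjusted over the list alone, among them Ptgr1 at log2 0.65, Prdx6 at 0.53 and Gclm at 0.46. Cytokines had 9 lower of 21 with adjusted p = 0.0612 with an estimated correlation, and 12 adjusted over the list alone. Camera with an estimated correlation called chemokines (1 higher and 8 lower of 21, median -0.52, p = 0.0492) and macrophage identity genes (1 higher and 9 lower of 20, median -0.16, p = 0.0201) lower. The limma camera chemokine call ended with RLE factors (adjusted p = 0.0508) and without LPS replicate 1 (0.0675), LPS replicate 2 (0.0676), CA replicate 1 (0.0634) or CA replicate 3 (0.0815), and the macrophage identity call ended without CA replicate 1 (0.0634) or CA replicate 3 (0.0643). Leaving out each library in turn, 5 to 9 macrophage identity genes were lower. In all 1023 genes were called, 305 higher and 718 lower. That number was 642 without LPS replicate 1, 541 without LPS replicate 2 and 434 in a model of only the groups compared, and 882 without the LPS + CA replicate 2 that stood apart, 691 of them shared in the same direction.

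CGA with LPS against LPS alone asked the same of chlorogenic acid, and few genes were called. Isg15, an interferon-induced ubiquitin-like gene (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), fell 1.41-fold from 306 ± 37.8 to 217 ± 10.5 CPM (n = 3). Usp18, which encodes the protease that removes ISG15, fell from 601 ± 80.4 to 420 ± 33.5 CPM and Ccl5 from 658 ± 58.1 to 520 ± 36.0 CPM. Sstr5 rose from 3.03 ± 0.709 to 5.28 ± 0.704 CPM. Cdkn1a fell by a log2 of 0.23. In edgeR the adjusted p was 0.0251 for Isg15, 0.0341 for Usp18, 0.0118 for Ccl5 and 0.0489 for Sstr5. Among genes not called, Cxcl10 stood at log2 -0.54 (adjusted p = 0.0732), Ifit1 at -0.50 (0.0964), Nos2 at -0.34 (0.32), Il1b at -0.23 (0.664), Tnf at -0.24 (0.715) and Nqo1 at 0.34 (0.0735). Neither were Srxn1 at 0.22 (0.0856), Gclm at 0.19 (0.144), Slc7a11 at 0.23 (0.354), Hmox1 at 0.29 (0.474), Ccl2 at -0.37 (0.294), Il6 at -0.20 (0.494), Ptgs2 at -0.02 (0.927), Il10 at 0.04 (0.955) and Ifnb1 at -0.56 (0.841).

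Chemokines were the only list called lower with CGA by camera with an estimated correlation (4 of 21 lower, 0 to 7 when each library was left out in turn, 10 adjusted over the list alone, median -0.34, adjusted p = 0.0332). Of 46 interferon genes 13 were lower (median -0.38, adjusted p = 0.0742 with an estimated correlation), and 45 adjusted over the list alone, and with each of the 6 libraries left out in turn from 0 to 37 were lower. In all 96 genes were called, 9 higher and 87 lower. The call count was 2 without LPS replicate 1, 0 without LPS replicate 2 (edgeR, with 896 genes at an unadjusted p under 0.05), 233 without LPS replicate 3, 11 without CGA replicate 1, 63 without CGA replicate 2, 0 without CGA replicate 3 (1121 genes unadjusted), 197 with a replicate term, 283 in a model of only the groups compared, 290 with no filter and 262 by DESeq2. The limma camera chemokine call ended without LPS replicate 1 (adjusted p = 0.101), CGA replicate 1 (0.094) or CGA replicate 3 (0.0591).

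CACys with LPS against LPS alone asked what the caffeic acid adduct altered. Il19, a cytokine gene of the interleukin 10 family (ENSMUSG00000016524, chromosome 1, 130932656 to 130945457), rose from 1.94 ± 0.454 to 6.56 ± 1.93 CPM (n = 3). Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024970) rose from 5.81 ± 0.293 to 11.15 ± 0.0549 CPM. Cxcl2, a neutrophil chemokine gene (ENSMUSG00000058427, chromosome 5, 90903899 to 90905938), fell from 4246 ± 151 to 2127 ± 127 CPM, and Ptgs2 fell from 2199 ± 116 to 1562 ± 52.1 CPM. Fcgr1, the high-affinity Fc receptor gene (ENSMUSG00000015947, chromosome 3, 96282909 to 96293969), rose from 116 ± 27.1 to 278 ± 38.7 CPM. Bnip3, a hypoxia-induced mitophagy gene, rose from 20.1 ± 3.38 to 57.1 ± 9.08 CPM, and Tfec, a macrophage transcription factor gene, fell from 5.36 ± 0.397 to 1.77 ± 0.193 CPM. The edgeR adjusted p was 7.2e-05 for Il19, 2.56e-05 for Il10, 1.79e-13 for Cxcl2, 5.38e-08 for Ptgs2 and 0.000219 for Fcgr1.

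Of the 46 interferon genes 33 were called higher with CACys (median 0.39), while the list had a camera adjusted p = 0.261 with an estimated correlation. Adjusted over the list alone 40 were higher, and from 19 to 40 were called over all genes when each library was left out in turn. Ifit1 rose to 708 ± 94.9 CPM (log2 0.54, edgeR adjusted p = 0.0123), Mx1, annotated as a transcribed pseudogene in this build, to 197 ± 26.8 CPM (0.78) and Ccl5 to 1055 ± 32.2 CPM (0.68). Immediate early genes had 11 of 28 higher (median 0.24, adjusted p = 0.155 with an estimated correlation), among them Dusp1, a MAP kinase phosphatase gene, at 140 ± 4.56 against 74.4 ± 7.19 CPM. Hypoxia and glycolysis genes had 16 of 30 higher (median 0.22, adjusted p = 0.155 with an estimated correlation), and ATF4 targets 2 higher and 13 lower of 33 (median -0.13, adjusted p = 0.254 with an estimated correlation), with 8 to 12 lower when each library was left out in turn. No list was called by camera with an estimated correlation, 4 had an unadjusted p under 0.05 and 9 were called with the preset correlation. Tnf at log2 -0.35 (adjusted p = 0.251), Il1b at 0.20 (0.451), Nos2 at 0.13 (0.543), Cxcl10 at 0.27 (0.175) and Hmox1 at 0.41 (0.0529) were not called. Neither were Ccl2 at -0.07 (0.808), Il6 at -0.12 (0.47), Ifnb1 at 0.82 (0.382), Slc7a11 at -0.19 (0.2), Gclm at -0.10 (0.306), Srxn1 at -0.08 (0.423) and Nqo1 at -0.06 (0.729). Cdkn1a rose to 480 ± 11.9 CPM (2.81e-06). In all 1890 genes were called, 1128 higher and 762 lower. That number was 1249 without CACys replicate 1 and 1223 without CACys replicate 2.

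CGACys with LPS against LPS alone asked the same of the chlorogenic acid adduct, which had the most calls of the 4 compounds. Krt16, an epithelial keratin gene (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902), rose 5.86-fold from 2.82 ± 0.239 to 16.6 ± 1.32 CPM (n = 3). Ccnd2, the cyclin D2 gene, rose from 6.64 ± 0.801 to 22.2 ± 2.32 CPM and Arrdc3, an arrestin-domain gene, from 4.70 ± 0.602 to 17.7 ± 1.90 CPM. Serpinb2, a plasminogen activator inhibitor gene (ENSMUSG00000062345, chromosome 1, 107500892 to 107525600), fell 3.29-fold from 52.3 ± 2.09 to 15.9 ± 0.995 CPM. Cxcl2 fell to 1786 ± 85.0 CPM and Ptgs2 to 1628 ± 58.5 CPM, while Il10 rose to 9.435 ± 0.875 CPM, Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722) to 585 ± 23.5 CPM, Nos2 to 572 ± 62.2 CPM and Hmox1 to 3222 ± 218 CPM. The edgeR adjusted p was 6.04e-12 for Krt16, 2.62e-12 for Serpinb2, 5.63e-16 for Cxcl2, 5.68e-11 for Cdkn1a, 0.013 for Nos2 and 0.00375 for Hmox1. Tnf at log2 -0.29 (adjusted p = 0.27), Il1b at 0.27 (0.202) and Srxn1 at 0.10 (0.238) were not called. Neither were Ifnb1 at 1.13 (0.129), Il6 at 0.12 (0.358), Ccl2 at 0.04 (0.865), Slc7a11 at -0.11 (0.399), Gclm at -0.04 (0.611) and Nqo1 at 0.00 (0.976).

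Lipid synthesis genes were lower with CGACys. Acat2, a cytosolic thiolase gene (ENSMUSG00000023832, chromosome 17, 12943042 to 12960725), fell from 41.3 ± 2.28 to 19.7 ± 0.898 CPM, and Fasn, the fatty acid synthase gene (ENSMUSG00000025153, chromosome 11, 120805958 to 120825166), fell 1.73-fold from 359 ± 27.2 to 207 ± 11.5 CPM. Lss, the lanosterol synthase gene (ENSMUSG00000033105, chromosome 10, 76531565 to 76557139), fell from 53.5 ± 0.872 to 34.1 ± 2.25 CPM. Camera called cholesterol synthesis (16 of 23 lower, median -0.28) and fatty acid synthesis (10 of 15 lower, median -0.36) lower, each with adjusted p = 0.0245 with an estimated correlation. By edgeR the adjusted p was 1.45e-12 for Acat2, 0.000984 for Fasn and 6.35e-09 for Lss.

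Of 46 interferon genes 45 were called higher with CGACys (median 0.66), while the list had a camera adjusted p = 0.213 with an estimated correlation. Rsad2 rose 2.45-fold from 1843 ± 208 to 4520 ± 352 CPM and Ifit1 from 487 ± 68.0 to 952 ± 86.3 CPM, and Cxcl10 rose to 632 ± 68.4 CPM, Cxcl11 to 106 ± 11.6 CPM and Ccl5 to 1439 ± 33.0 CPM. Antigen presentation genes had 11 of 17 higher (median 0.33, adjusted p = 0.254 with an estimated correlation), with the peptide transporter gene Tap1 at log2 1.02, and immediate early genes 17 higher and 2 lower of 28 (median 0.39, adjusted p = 0.139 with an estimated correlation). The p53 targets had 10 higher and 1 lower of 18 (median 0.21, adjusted p = 0.139 with an estimated correlation). In all 3854 genes were called, 2130 higher and 1724 lower, of which 302 changed at least 2-fold, and the balance turned in a model of only the groups compared (2154 and 2301). Markers of other cell types also changed: the fibroblast markers Col6a1 (log2 1.24, adjusted p = 0.0315) and Pdgfra (0.62, 0.00704) and the neutrophil marker Ly6g (1.19, 0.0105) were higher by edgeR, and S100a8 (-0.94, 0.000107) and Camp (-0.94, 0.0162) were lower. Leaving out each library in turn, 1 to 2 fibroblast markers were higher. Of the neutrophil and mast cell markers 0 to 1 were higher and 1 to 2 lower. Col6a1 and Camp averaged 0.549 and 2.36 CPM with LPS alone, and all libraries came from the RAW264.7 line.

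**Figure D2:**
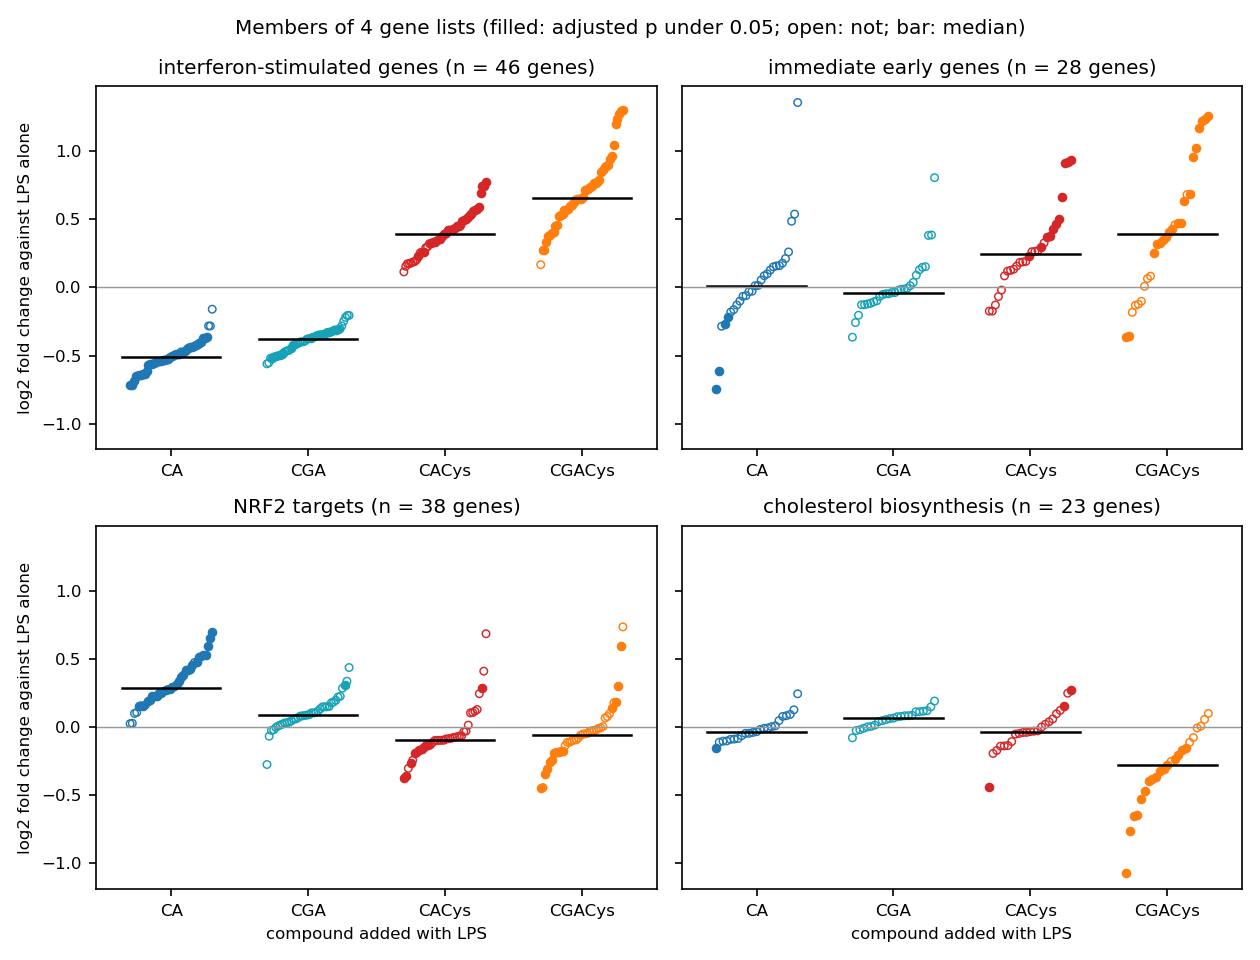
Log2 fold change against LPS alone for each member of the interferon-stimulated (46), immediate early (28), NRF2 target (38) and cholesterol synthesis (23) lists with each compound, filled where the edgeR adjusted p was under 0.05, with a bar at the median, n = 3 libraries per group. Interferon medians were -0.51 with CA, -0.38 with CGA, 0.39 with CACys and 0.66 with CGACys.

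CACys against CA, both with LPS at 100 µM for 6 h, asked what the cysteine adduct changed relative to its parent acid. Fcgr1 was 4.21-fold higher with CACys, at 278 ± 38.7 against 66.1 ± 4.56 CPM (n = 3, edgeR adjusted p = 1.13e-06). Maf, a macrophage transcription factor gene, averaged 114 ± 15.5 against 36.1 ± 3.68 CPM (adjusted p = 3.62e-08), and Il23r 5.06 against 1.45 CPM. Il10 was 2.30-fold higher and Nos2 was higher by a log2 of 0.93 (SE 0.12), Il1b by 0.88, Cxcl10 by 0.88, Ccl2 by 0.61, Cdkn1a by 0.59 and Ifit1 by 1.07, and Ptgs2 was lower at -0.55 and Cxcl2 at -1.15. Srxn1 was lower at -0.68, Nqo1 at -0.58, Gclm at -0.55 and Slc7a11 at -0.48. Tnf (log2 -0.29, 95% interval -0.68 to 0.10), Il6 (0.15, -0.05 to 0.34), Ifnb1 (1.34, adjusted p = 0.088) and Hmox1 (-0.28, adjusted p = 0.129) did not differ by the test.

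Of the 46 interferon genes 46 were higher with CACys than with CA (median 0.90, camera adjusted p = 0.138 with an estimated correlation). Of 38 NRF2 targets 32 were lower (median -0.35, adjusted p = 0.138 with an estimated correlation). Without CA replicate 2 these were 46 and 31. Camera with an estimated correlation called 0 lists, against 10 with an unadjusted p under 0.05 and 17 with the preset correlation. The comparison had 3589 called genes, 2011 higher and 1578 lower, and 2145 in a model of only the groups compared (1402 and 743). The balance turned with upper-quartile factors (1835 and 1994). Col6a1 (log2 1.35, edgeR adjusted p = 0.0373) and Pdgfra (0.81, 0.00104) were higher and S100a8 (-0.84, 0.00011) was lower with CACys, and 1 to 2 fibroblast markers were higher when each library was left out in turn.

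CGACys against CGA, both with LPS at 100 µM for 6 h, asked the same for chlorogenic acid. Krt16 was 7.63-fold higher with CGACys, at 16.6 ± 1.32 against 2.19 ± 0.731 CPM (n = 3, edgeR adjusted p = 2.5e-13). Fasn averaged 207 ± 11.5 against 418 ± 14.9 CPM (adjusted p = 0.000101) and Acat2 19.7 ± 0.898 against 43.2 ± 1.08 CPM (1.53e-13). Cxcl10 was 2.38-fold higher, and Ifit1 was higher by a log2 of 1.47 (SE 0.13), Cdkn1a by 0.92, Nos2 by 0.79, Il10 by 0.66, Il1b by 0.50, Ccl2 by 0.41 and Il6 by 0.32. Ifnb1 averaged 0.971 ± 0.162 against 0.289 ± 0.125 CPM (adjusted p = 0.0217). Ptgs2 was lower at -0.41, Slc7a11 at -0.34, Nqo1 at -0.33 and Gclm at -0.23. Tnf (log2 -0.04, 95% interval -0.43 to 0.35), Srxn1 (-0.12, adjusted p = 0.13) and Hmox1 (0.31, 0.0894) did not differ by the test.

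Camera with an estimated correlation called cholesterol synthesis (18 of 23 lower, median -0.36, adjusted p = 0.0163) and fatty acid synthesis (12 of 15 lower, median -0.42, p = 0.0142) lower with CGACys than with CGA. Of 46 interferon genes 46 were higher, with adjusted p = 0.114 with an estimated correlation, and of 38 NRF2 targets 21 were lower (median -0.16, adjusted p = 0.395 with an estimated correlation). In all 4383 genes were called, 2415 higher and 1968 lower, and the balance turned in a model of only the groups compared (2583 and 2615). Of 5 tested fibroblast markers 3 were higher (camera adjusted p = 0.114 with an estimated correlation), and 2 to 3 when each library was left out in turn. These were Col6a1 (log2 2.26, edgeR adjusted p = 0.000406), Pdgfra at 0.88 and Fn1 at 0.27. The B cell marker Pax5 (1.79, 0.00417) was higher and S100a8 (-1.11, 5.08e-06) was lower with CGACys.

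CGA against CA, both with LPS at 100 µM for 6 h, asked whether the parent acids differed. Srxn1 was lower with CGA than with CA at log2 -0.37 (SE 0.06, n = 3, edgeR adjusted p = 0.00144) and Gclm (ENSMUSG00000028124, chromosome 3, 122245487 to 122267215) at -0.27 (adjusted p = 0.0163). Abca1, a cholesterol exporter gene, averaged 161 ± 12.8 against 99.1 ± 22.6 CPM (adjusted p = 0.0256). Ticam2, a Toll-like receptor adaptor gene (ENSMUSG00000056130, chromosome 18, 46558231 to 46574533), averaged 2.93 ± 0.402 against 1.48 ± 0.138 CPM (0.036) and Serpinb2 57.5 ± 4.33 against 37.5 ± 6.88 CPM (0.000624). Ifit1 (log2 0.03, 95% interval -0.24 to 0.31), Cxcl10 (0.07, -0.20 to 0.34), Nos2 (0.46, 0.19 to 0.72, adjusted p = 0.0878), Il1b (0.46, 0.13 to 0.78, adjusted p = 0.149), Tnf (-0.19, -0.58 to 0.20) and Hmox1 (-0.41, -0.69 to -0.13, adjusted p = 0.14) did not differ by the test. Neither did Ccl2 (0.31, 0.03 to 0.59), Il10 (0.30, -0.00 to 0.61), Il6 (0.07, -0.13 to 0.27), Ptgs2 (-0.08, -0.18 to 0.02), Ifnb1 (-0.04, -1.38 to 1.30), Nqo1 (-0.18, -0.36 to -0.00), Slc7a11 (-0.07, -0.26 to 0.12) and Cdkn1a (-0.04, -0.15 to 0.07).

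NRF2 targets had 13 of 38 lower with CGA than with CA (median -0.21, camera adjusted p = 0.106 with an estimated correlation), and 26 adjusted over the list alone. Interferon genes had a median of 0.13 and adjusted p = 0.569 with an estimated correlation. In all 183 genes were called, 84 higher and 99 lower, while camera with an estimated correlation called 0 lists, against 8 with an unadjusted p under 0.05, 14 with the preset correlation and 1 with a replicate term. The gene count was 448 without CA replicate 1, 87 without CA replicate 2, 1063 without CA replicate 3, 87 without CGA replicate 1, 45 without CGA replicate 2, 57 without CGA replicate 3, 3 in a model of only the groups compared, 614 with no filter and 414 by DESeq2. The balance turned with no filter (361 higher and 253 lower), by DESeq2 (230 and 184) and without CA replicate 1 (240 and 208) or 3 (596 and 467). The NRF2 targets had 7 lower without CA replicate 2 and from 5 to 20 when each library was left out in turn.

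CGACys against CACys, both with LPS at 100 µM for 6 h, asked whether the adducts differed. Acat2 was lower with CGACys at 19.7 ± 0.898 against 30.5 ± 1.51 CPM (n = 3, edgeR adjusted p = 3.14e-06) and Lss at log2 -0.52 (SE 0.07, 1.87e-05). Krt16 averaged 16.6 ± 1.32 against 7.98 ± 0.601 CPM (0.000109) and Gbp5, a guanylate-binding protein gene, 356.4 ± 25.01 against 218.3 ± 23.95 CPM (0.000798). Cdkn1a was higher by a log2 of 0.29 (0.00244) and Ccl5 by 0.45 (0.000109). Cxcl10 (log2 0.44, 95% interval 0.18 to 0.70, adjusted p = 0.0973), Ifit1 (0.43, 0.16 to 0.70, 0.117), Ptgs2 (0.06, -0.04 to 0.16), Il10 (-0.24, -0.51 to 0.03) and Tnf (0.06, -0.33 to 0.45) did not differ by the test. Neither did Nos2 (0.32, 0.05 to 0.58, adjusted p = 0.245), Il1b (0.08, -0.24 to 0.40), Il6 (0.24, 0.05 to 0.44, 0.229), Ccl2 (0.10, -0.18 to 0.38), Ifnb1 (0.31, -0.72 to 1.33), Hmox1 (0.18, -0.10 to 0.46), Nqo1 (0.07, -0.12 to 0.26), Gclm (0.05, -0.07 to 0.17), Slc7a11 (0.07, -0.11 to 0.26) and Srxn1 (0.18, 0.06 to 0.31, 0.132).

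Camera with an estimated correlation called cholesterol synthesis (15 of 23 lower, median -0.30, adjusted p = 0.000434) and fatty acid synthesis (4 of 15 lower, 1 to 4 when each library was left out in turn, 10 adjusted over the list alone, median -0.22, p = 0.00274) lower with CGACys than with CACys. Of 46 interferon genes 7 were higher (median 0.28, adjusted p = 0.208 with an estimated correlation), 2 to 8 when each library was left out in turn, and 35 adjusted over the list alone. In all 239 genes were called, 135 higher and 104 lower. That number was 157 without CACys replicate 1, 88 without CACys replicate 3, 87 without CGACys replicate 1, 95 without CGACys replicate 2, 560 in a model of only the groups compared, 409 with no filter and 370 by DESeq2.

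The adduct effect in CGA minus the adduct effect in CA asked whether the adducts differed from their parent acids by different amounts. Krt16 rose more in CGA, by a log2 of 1.65 (SE 0.25), and Serpinb2 fell more, at -1.23 (SE 0.14). Marco, a macrophage scavenger receptor gene (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), differed by -1.02 (SE 0.08), averaging 289 ± 26.1 CPM with CA, 366 ± 22.2 with CACys, 395 ± 17.3 with CGA and 246.5 ± 10.1 with CGACys (n = 3). Slc30a1, a zinc exporter gene, differed by 0.57, averaging 122 ± 1.87, 135 ± 5.27, 105 ± 2.51 and 172 ± 4.84 CPM in the same order. By edgeR the adjusted p was 0.000321 for Krt16, 1.58e-05 for Serpinb2, 8.45e-09 for Marco and 1.58e-05 for Slc30a1. Nos2 (log2 -0.14, 95% interval -0.52 to 0.23), Tnf (0.25, -0.30 to 0.80) and Ptgs2 (0.14, adjusted p = 0.338) were not called. Neither were Il1b (-0.38, 0.42), Il6 (0.18, 0.57), Il10 (-0.54, 0.164), Ccl2 (-0.21, 0.641), Cxcl10 (0.37, 0.333), Ifnb1 (0.35, 0.884), Ifit1 (0.40, 0.308), Hmox1 (0.59, 0.132), Nqo1 (0.25, 0.356) and Slc7a11 (0.14, 0.637), while Srxn1 (0.56, 0.000514), Gclm (0.32, 0.0331) and Cdkn1a (0.33, 0.0141) were.

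Camera with an estimated correlation called cholesterol synthesis (14 of 23 lower, adjusted p = 0.000995), fatty acid synthesis (5 of 15 lower, 0.00677), mitosis (0 of 29 called by edgeR, 7 lower at an unadjusted p under 0.05, 0.00891) and macrophage identity (5 of 20 lower, 0.0172) lower and p53 targets (3 of 18 higher, 0.0146) and ATF4 targets (3 of 33 higher, 0.044) higher in the adduct effect of CGA. The limma camera ATF4 call ended with RLE factors (adjusted p = 0.057) and without any 1 of 10 of the 12 libraries compared (0.0544 to 0.0925), and the macrophage identity call without CA replicate 1 (0.0867). Interferon genes had a median of 0.20 (adjusted p = 0.619 with an estimated correlation), and of 38 NRF2 targets 8 were higher (median 0.21, adjusted p = 0.198 with an estimated correlation), 18 adjusted over the list alone. Leaving out each library in turn, 4 to 15 NRF2 targets were higher, 1 to 7 ATF4 targets and 1 to 3 p53 targets were higher, and 3 to 7 fatty acid synthesis genes, 4 to 7 macrophage identity genes and 0 to 1 mitosis genes were lower. In all 289 genes were called, 145 higher and 144 lower, and this balance turned with RLE factors (143 and 148), with no filter (221 and 236), by DESeq2 (205 and 231) and without CA replicate 1 (196 and 242) or 3 (222 and 297), CACys replicate 1 (96 and 98) or CGACys replicate 1 (76 and 86). That number was 438 without CA replicate 1, 519 without CA replicate 3, 191 without CGA replicate 1, 170 without CGA replicate 2, 180 without CGA replicate 3, 182 without CACys replicate 2, 162 without CGACys replicate 1, 183 without CGACys replicate 3, 166 in a model of only the groups compared, 457 with no filter and 436 by DESeq2.

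**Figure D3:**
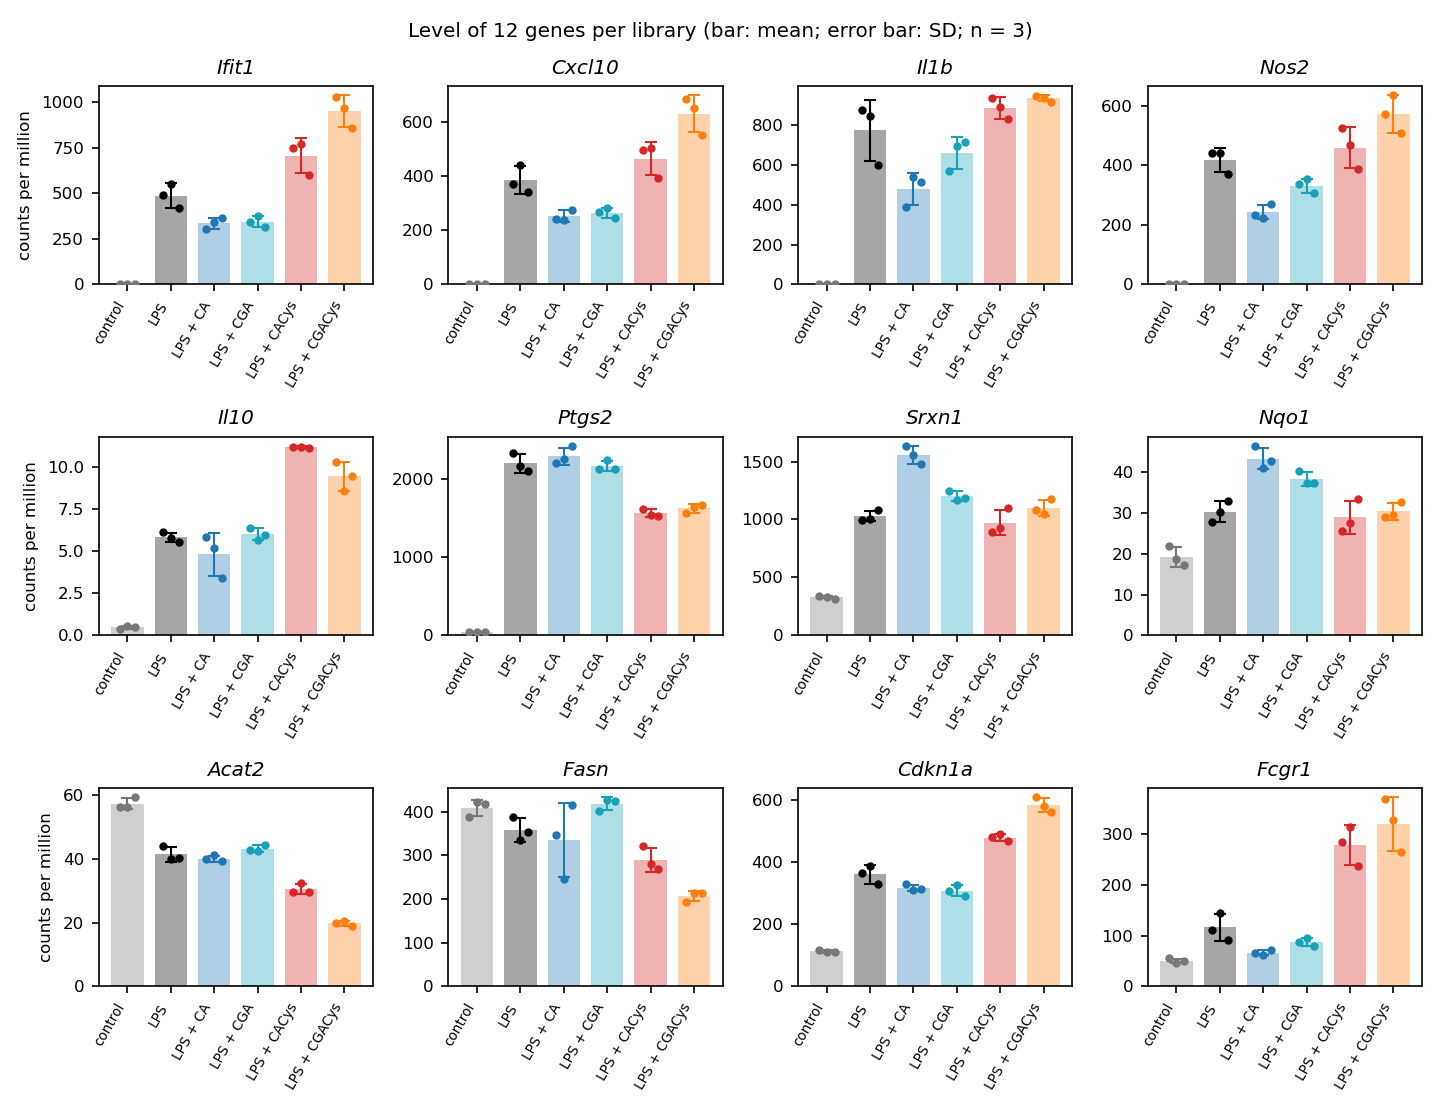
CPM per library for 12 genes in the 6 groups, with a bar at the mean and error bars of SD, n = 3. Ifit1 averaged 487 CPM with LPS and 952 CPM with LPS + CGACys, and Fasn 359 CPM and 207 CPM.

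Genes changed by more than one compound were counted from the calls against LPS. CACys and CGACys shared 1734 genes in the same direction, 1034 higher and 700 lower, with 0 in opposite directions, where 181.3 and 99.14 would be shared if the calls were independent. CA and CGA shared 84 genes, 7 higher and 77 lower, where 0.2072 and 4.714 would be shared. CA and CACys shared 101 genes in the same direction and 312 in opposite directions, and CA and CGACys 166 and 455. These pairs have the LPS libraries in common, which alone makes their log2 changes correlate. Over all tested genes the correlation of CA with CGA was 0.534, against a mean of 0.521 and a highest of 0.557 in 20 simulations of unchanged groups, while the covariance was 0.0467, against a highest of 0.0333. The correlation of CACys with CGACys was 0.764, against a highest of 0.562, and the covariance 0.114, against a highest of 0.0359. The correlations of CA with CACys and with CGACys were 0.253 and 0.177, against a simulated mean of 0.517 for each. The covariances were 0.0282 and 0.0245, against means of 0.0313 and 0.0312. By DESeq2 the correlations were 0.213 and 0.321, and the covariances 0.0274 and 0.0552. The simulations were fitted by edgeR only, with genes drawn independently. Where CA with CGACys lay against them thus depended on the method. CACys against CA and CGACys against CGA have no library in common and shared 2414 genes in the same direction, 1495 higher and 919 lower, against 23 in opposite directions.

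The genes that LPS raised at least 2-fold numbered 1341. With CA 364 of them were lower and 50 higher than with LPS alone, and with CGA 68 were lower and 2 higher. With CACys 116 were lower and 258 higher, and with CGACys 142 and 492. Independent calls would give 72.66 lower and 30.87 higher with CA, and 8.804 and 0.9108 with CGA. They would give 77.11 and 114.2 with CACys, and 174.5 and 215.6 with CGACys. The 142 lower with CGACys were thus fewer than independent calls would give. Cxcl2, Cxcl3 and Ptgs2 were lower with both adducts while Ifit1, Mx1 and Rsad2 were higher. The median log2 change of the 1341 genes was -0.247 with CA, -0.155 with CGA, 0.0877 with CACys and 0.242 with CGACys. LPS was on one side of both comparisons, and simulated means from that alone ran from -0.012 to -0.0139.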

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

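The splits of the libraries and the tests of the difference between adduct effects were set before the data were examined, and the tests of why interferon genes moved, of histone genes, and of LPS + CA replicate 2 were chosen after the result was seen. Each difference between adduct effects was picked out because the effect of the cysteine adduct differed between the acids by an edgeR or camera test of the difference itself.

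The adduct effect in CGA minus that in CA had 289 called genes. When the acid labels were permuted within parents and within adducts, 1 of 100 splits, the real one, gave as many. The highest other gave 132. A count this high was thus rare among the splits, but chance is not excluded. Permuted groups mostly mixed the acids, so real differences between acids widened their spread and could lower their counts. Cholesterol synthesis genes differed by a median log2 of -0.3757, fatty acid synthesis by -0.3078, macrophage identity by -0.1223 and mitosis by -0.1041, while p53 targets differed by 0.1792 and ATF4 targets by 0.16.

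Sterol and fatty acid genes had a lower adduct effect in CGA than in CA. Acat2 changed by log2 -0.39 in CA and -1.13 in CGA, a difference of -0.737 (edgeR adjusted p = 1.94e-05). Lss differed by -0.67 (4.31e-05), Mvd, the mevalonate decarboxylase gene, by -0.59 (0.000186), Aacs, an acetoacetyl-CoA synthetase gene, by -0.545 (0.0018) and Fads2, a desaturase gene, by -0.5 (0.0115). Scd2, a stearoyl-CoA desaturase gene, stood at 0.495 in CA and -0.28 in CGA, a difference of -0.775 (0.0141).

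Of the p53 list 3 of 18 members and of the ATF4 list 3 of 33 were called higher in this difference, and the ATF4 list call ended with RLE factors (camera adjusted p = 0.057) and without any 1 of 10 of the 12 libraries (0.0544 to 0.0925). Cdkn1a changed by 0.59 in CA and 0.92 in CGA, a difference of 0.327 (edgeR adjusted p = 0.0141), and Mdm2, the p53 ligase gene, differed by 0.265 (0.0466). Plk2, a polo-like kinase gene, stood at -0.314 in CA and 0.359 in CGA, a difference of 0.673 (0.00012). Atf3 differed by 0.463 (0.00012), Ppp1r15a, the GADD34 gene, by 0.447 (0.0202) and the amino acid transporter gene Slc3a2 by 0.253 (0.0207). Among NRF2 targets Srxn1 stood at -0.68 in CA and -0.12 in CGA, a difference of 0.556 (0.000514), and Gclm differed by 0.322 (0.0331). Both genes were called lower with CGA than with CA, while neither differed by the test between the adducts. Among macrophage genes Adgre1, the F4/80 gene, differed by -0.522 (0.00012) and the lysozyme gene Lyz2 by -0.381 (0.00932).

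For the other comparisons, 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In each of them 1 of 10 splits, the real one, gave the real number of called genes. The other splits mixed the 2 groups, so a real difference widened their spread and lowered their counts. Their low counts are thus no support for the real groups. The real number and the highest of the other splits were 8243 and 0 for LPS against control, 1023 and 2 for CA, 96 and 0 for CGA, 1890 and 0 for CACys and 3854 and 0 for CGACys against LPS. They were 3589 and 1 for CACys against CA, 4383 and 0 for CGACys against CGA, 183 and 1 for CGA against CA, and 239 and 0 for CGACys against CACys.

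Most interferon genes were called lower with CA and higher with CGACys, while the list had a camera adjusted p = 0.0612 and 0.213 with an estimated correlation, and scaling or a change in the whole LPS response could each explain those calls. The median nearest to 0 under RLE and upper-quartile factors was -0.491 with CA and 0.656 with CGACys. The medians thus do not rest on the choice among these factors. None of the factors can detect a shift in total RNA, so that was not tested. Genes that LPS lowered at least 2-fold had a median of 0.141 with CGACys, 223 higher and 99 lower. Simulations with no change gave 0.0204 to 0.0388, and a stronger LPS response would put the median below that range. Simulated genes were drawn independently, so the range is narrower than it would be for genes that move together. The median was also raised with CGA (0.0884) and CACys (0.162), so its rise was not particular to CGACys. Genes that LPS raised at least 2-fold went the way of a stronger response, 492 higher and 142 lower with CGACys. Over all 4187 genes that LPS lowered, 602 were higher and 672 lower. A stronger LPS response as a whole is thus left open. With CA the genes that LPS lowered at least 2-fold had a median of 0.0581, against at most 0.0389 with no change. Of these 1145 genes 29 were higher and 42 lower, so the median and the called genes point opposite ways. A weaker LPS response as a whole and changes in separate gene groups thus cannot be told apart.

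LPS + CA replicate 2 stood apart on the second component, 20.4 units from its nearest replicate, and depth or this 1 library's weight might account for the CA result. LPS + CGA replicate 2 was deeper, with 25624935 counts, and lay 6.08 units from its nearest replicate. It was also the farthest of its group, at 11.71 against 4.535 and 5.63. LPS + CA replicate 2 lay on the opposite side, at -28.38. A single other deep library cannot decide on depth. Without LPS + CA replicate 2, 691 of the 1023 genes called with CA were called in the same direction. That argues against this library alone making the changes. Why it stood apart was not settled by these tests.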

How the results depend on the processing

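The alternatives were set before the data were examined, except list members without LPS + CA replicate 2 and the interferon list under other scaling, which were chosen after the result was seen. No called value of the alternatives changed sign. Of 919 gene results, with 12279 alternative values in all, 892 had a value by DESeq2, 899 with the filter of 1 CPM and 908 with only the groups compared, and 919 under the other settings of the whole data. DESeq2 left 877 on their side of the threshold (4 lost and 11 gained a call), RLE factors 914 (5 and 0), upper-quartile factors 910 (8 and 1), the replicate term 904 (9 and 6), no filter 893 (19 and 7), a filter of 1 CPM in 3 libraries 896 (1 and 2) and only the groups compared 797 (104 and 7). Leaving out 1 library at a time gave 5211 values on their side, 674 lost and 19 gained.

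Counts of genes that moved by over 1.5 times were these. With only the groups compared they were 434 for CA, 283 for CGA, 2145 for CACys against CA, 3 for CGA against CA, 560 for CGACys against CACys and 166 for the difference between adduct effects. With no filter they were 290 for CGA, 614 for CGA against CA, 409 for CGACys against CACys and 457 for the difference. By DESeq2 they were 262, 414, 370 and 436 in the same order, and 197 for CGA with the replicate term. By DESeq2 CA and CGA shared 219 genes (84 by edgeR), CGA and CACys 16 (4), CGA and CGACys 17 (6), and 165 genes raised by LPS were lower with CGA (68).

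Leaving out each library in turn gave 541 to 1439 genes for CA, 0 to 233 for CGA (edgeR, 896 genes at an unadjusted p under 0.05 without LPS replicate 2 and 1121 without CGA replicate 3), 1223 to 1694 for CACys, 45 to 1063 for CGA against CA, 87 to 198 for CGACys against CACys and 162 to 519 for the difference. The camera lists ranged from 0 to 7 for CA and 0 to 3 for CGA. The cause was not tested.

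With the preset correlation camera called 19 lists for LPS, 12 for CA, 14 for CGA, 9 for CACys, 10 for CGACys, 17 for CACys against CA, 15 for CGACys against CGA, 14 for CGA against CA, 11 for CGACys against CACys and 13 for the difference. Those that hold with the estimated correlation were 7 for LPS (cytokines, chemokines, NF-kB, ATF4, iron and metal, S phase, mitosis), 2 for CA (chemokines, macrophage identity), 1 for CGA (chemokines), 2 each for CGACys against LPS, CGA and CACys (cholesterol and fatty acid synthesis) and 6 for the difference. RLE factors left 1 list for CA, and the replicate term gave 1 for CGA against CA. Leaving out each library kept both lipid lists called for CGACys, with adjusted p from 0.029 to 0.0496 against LPS by camera.

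Libraries shared only a replicate number. The residual correlation of 45 pairs with the same number averaged -0.00363, and 3 of 18 libraries correlated best with their own number, so no pairs were used. In depth, 16105817 counts was the lowest library total. Changes of 1.5-fold were found for 63 of 67 simulated genes with a mean of at least 50 counts in CA against LPS.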

Other observations

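Histone, Txnip, keratin-linked, metal, transporter and lipid oxidation genes in this part, and the tests on histone genes, were chosen after the result was seen. Replication-dependent histone genes lie in clusters, and 34 of them were tested. With CGACys 19 were higher than with LPS alone, with a median log2 of 1.09, and with CACys 9 were higher, with a median of 0.485. Against CGA 22 were higher with CGACys, with a median of 1.29. With CA and CGA the medians were -0.152 and -0.19. Hist1h1c, a linker histone gene, averaged 261.6 CPM with CGACys and 103.4 CPM with LPS alone (log2 1.34, edgeR adjusted p = 1.71e-12), and H1f0, a linker histone gene expressed outside S phase, differed by 0.63 (4.23e-09).

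More cells in S phase or more RNA without a poly(A) tail could raise histone transcripts with CGACys. The S phase list had a median of 0.129, and small RNAs without a tail had a median of -0.0801 over 15 RNAs whose median mean count was 13.7. These explanations and a change in histone transcription cannot be told apart. The S phase shift is small beside the histone median of 1.09. The small RNAs had too few counts for a decision, the floor having been 20. The histone genes were only a little above that floor, with a median mean count of 26.5.

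Some single genes also differed with the adducts. Txnip, the thioredoxin-interacting protein gene, rose from 187.7 to 392.7 CPM with CGACys (edgeR adjusted p = 1.94e-15) and to 317 CPM with CACys, next to its relative Arrdc3. The cornified envelope genes Sprr1a, Sprr2d and Sprr2e rose by log2 1.32, 1.31 and 1.49 with CGACys, as Krt16 did. With CACys these Sprr genes rose by 1.04, 0.962 and 1.141 and Krt16 by 1.496. The Sprr genes did not differ between the adducts by the edgeR test. Slc6a12, a betaine transporter gene, fell by a log2 of 1.40 with CGACys and 1.14 with CACys. Cpt1a, a gene of fatty acid oxidation, rose by 1.17 with CGACys, while Fasn fell. With CACys Cpt1a rose by 0.58. The metallothionein genes Mt1 and Mt2 rose by 0.54 and 0.77 with CGACys. Mt1 also rose with CA, by 0.44, and with CACys, by 0.33, and Mt2 stood at 0.03 with CACys (edgeR adjusted p = 0.951). The iron and metal list had 7 higher and 6 lower of 20 with CGACys (camera adjusted p = 0.939 with an estimated correlation).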
